A study of Mus musculus with 46 samples.

How the data were processed

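Expression was measured in mouse lung with Agilent 4x44K arrays that carry 2 dyes. Each of 46 arrays compared Cy5-labelled RNA of the left lung lobe of 1 animal with a Cy3-labelled reference pooled from all samples, and the dyes were never swapped. The animals fell into 8 groups by genotype, sex and diet, with 5 to 6 animals each. Knockout animals lacked the beta-carotene cleaving enzyme Bco1 (Bcmo1 in the files) and came from a mixed B6;129S background, while wild-type animals were B6129SF1 hybrids, so that strain and genotype went together in every comparison. Animals ate a control diet or the same diet with 150 mg beta-carotene per kg for 14 weeks from 5 weeks of age, both with 1500 IU vitamin A per kg and 10% fat. The labels' protocols state 1000 ng of RNA per labelling.

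The deposited scanner files hold raw foreground and background intensity values of both dyes for 45018 spots per array. Per the file headers they were made with Feature Extraction 9.5.1.1, while the submitters' processing notes name version 9.5.3.1. The authors' deposited table holds log2 values of 31128 features. Each of its columns has a median of 9.471, and it correlated with log2 Cy5 at 0.99 or more on each array and with the log ratio at 0.16 at most. It was therefore read as normalized log2 Cy5 intensity without the reference, and used only as an alternative. Its background handling and normalization steps beyond the notes are not given in the sources used here.

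Signals were corrected for background with normexp and an offset of 50, from mean foreground and median background. The 1639 control spots were left out, 1021 non-uniform spots over all arrays were set to missing, and log2 Cy5/Cy3 ratios were normalized by loess within each array. Spots of 1 probe were averaged. A probe was kept if its Cy5 signal was well above background on at least 5 of the 46 arrays, which left 29214 of 41174 probes. Each gene was represented by its brightest kept probe, a choice that mattered for 6788 genes with more than 1 such probe. Tests covered 19379 genes with at least 3 values in each group. Of these, 15665 carried a current symbol of the reference, and the others kept the name in the files. Probe positions are those of the files, on mouse build mm8.

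The percentage of probes well above background ranged over the arrays from 50.3 to 71.4 for Cy5 and from 48.5 to 64.2 for Cy3. The median Cy5 signal ranged from 214.3 to 355.9, over a median background of 48 to 64.5, and 1 to 3 probes per array were saturated.

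limma 3.58.1 in R 4.3.3 fitted a linear model with a mean per group to all arrays. Its moderated variances follow intensity and pool all groups, so SEs and p are too small for interferon genes of control knockout females. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes in each of 13 comparisons. Diet changes of knockout females and males were correlated across genes, with exact permutation of diet labels within each sex. No fold is given where a compared group was below background on every array.

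The comparisons, the processing, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. In each comparison the rule named the targeted gene and the 10 genes with a symbol that changed most in each direction among those passing. Where fewer than 5 genes passed, it added the 5 with the smallest p in each direction, and of each described list it took up to 2 members with the smallest p per direction. Genes named outside this rule are said to be so, and some results that the rule would name are not reported here. The 39 gene lists covered pathways, lung cell types and tissues that dissection can carry over, and were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Lists for olfactory receptors, protocadherins, Wnt signalling and inflammation follow gene families that the study's group reported from lungs of this experiment, and are no independent evidence. The 6 passing lists with the smallest p, and any passing with the estimated correlation, were described per comparison. For 8 lists the mean per array was also compared by 48 exact permutation tests. Both choices were made after the list results were seen.

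The fit was tested on simulated data that kept the residual spread of each gene, with the same spread in all groups and independent genes. Among 100 genes changed by 0.5 on the log2 scale, it recovered 90% for diet in knockout females, 89% for diet in wild-type females, 73% for the difference between the sexes in the diet change of knockouts and 98% for genotype. Among 100 genes changed by 1, it recovered 98%, 96%, 93% and 100%. At most 11 genes were called wrongly.

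Alternatives were no background subtraction, Feature Extraction's own processed signals, Cy5 alone with quantile normalization, the authors' table, no filter on dim probes, the mean of a gene's probes, slide as a fixed or random block, a replicate block, only the compared groups in the fit, and each array left out in turn. A further 3 were added after seeing the data: the position of the array on the slide as a block, since position and diet went together in the knockout groups, 3 doubtful arrays left out, and each array left out in turn for the described lists. The doubtful arrays were replicate 2 of the knockout females on beta-carotene, replicate 4 of the wild-type males on control diet and replicate 3 of the knockout males on beta-carotene, where genes of the other sex stood apart towards 0. The part of Bco1 that was deleted, the cage and the litter of each animal are not given in the sources used here. Files were read with the R package data.table, version 1.17.8, and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.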

Results

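The study asks what dietary beta-carotene does in the lungs of male and female mice that can or cannot cleave it with Bco1. Log2 ratios of lung RNA over a pooled reference were compared between 8 groups. Wild-type females numbered 5 on each diet, and knockout females, wild-type males and knockout males numbered 6 on each diet. Arrays lay on 12 slides of 4 positions. Knockout males on beta-carotene always lay at positions 1 or 4 and those on control diet at positions 2 or 3, so results with position as a block are given beside the diet changes of knockouts. Genotype accounted for 0.834 of the variance of the first principal component, which held 24.2% of the total, and diet for at most 0.021 of any of the first 4 components. Slide accounted for 0.333, 0.69, 0.639 and 0.292 of these 4.

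The probe for Bco1 itself (chromosome 8, 120019073 to 120019132) gave higher ratios in knockout lungs than in wild-type lungs. Its log2 ratio ranged from 0.01 to 0.36 in knockouts and from -0.41 to 0.00 in wild types. The difference was 0.48 ± 0.07 (SE, n = 6 and 5) in females on control diet, with adjusted p = 3.31e-06, and 0.41 ± 0.07 (SE, n = 6 and 6) in males, with adjusted p = 3.07e-05. Over all groups the difference was 0.44 (adjusted p = 1.2e-13). With beta-carotene Bco1 changed by -0.02 in knockout females (adjusted p = 0.998) and by 0.01 or less in the other groups (adjusted p = 0.999 to 1), and between the sexes by 0.04 (adjusted p = 0.548). Its differences of differences ranged from -0.02 to 0.07 (adjusted p from 0.851 to 1). Bco1 was above background on no array of the wild-type males and on 1 array in each diet group of the wild-type females, so the size of these genotype differences is uncertain. Which part of the gene was deleted is not given in the sources used here, so this probe checks nothing about the knockout.

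Beta-carotene in knockout females went with lower levels of interferon-induced genes. Ifi27l2a was 3.99-fold lower (log2 -2.00 ± 0.38, SE, n = 6 and 6), with a mean log2 ratio of 0.01 ± 0.60 (SD) on beta-carotene and 2.00 ± 1.49 on control diet. Slfn4, an interferon-inducible gene of myeloid cells, was 2.67-fold lower (log2 -1.42 ± 0.20, SE), and Rtp4, a receptor chaperone that interferon induces, 2.71-fold lower (log2 -1.44 ± 0.22, SE). The ubiquitin-like modifier Isg15 was 2.73-fold lower (log2 -1.45 ± 0.29, SE). The transcription factor Irf7 was 2.65-fold lower (log2 -1.41 ± 0.34, SE), and Acod1, which makes itaconate in activated macrophages, 2.80-fold lower (log2 -1.49 ± 0.30, SE).

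In all, limma called 108 of 19379 genes in knockout females, 14 higher and 94 lower with beta-carotene (median size 0.60 in log2). Adjusted p was 0.000183 for Slfn4, 0.000936 for Rtp4, 0.00795 for Ifi27l2a, 0.00901 for Isg15, 0.0112 for Acod1 and 0.0313 for Irf7. Ifit1 (log2 -1.53, adjusted p = 0.0119), Ifi44 (log2 -1.49, adjusted p = 0.0114), Oasl2 (log2 -1.37, adjusted p = 0.00901) and Oas1f (log2 -1.43, adjusted p = 0.0114) fell as well. Each gene named by rule here lay beyond the control mean in 6 of 6 arrays. For Isg15 and Oasl2 so did controls other than replicates 2 and 6. Of the genes that rose, Trim12a changed most (log2 3.08 ± 0.72, SE, 8.45-fold, adjusted p = 0.028). It ranged from -4.0 to 0.69 on control diet and 0.26 to 1.46 on beta-carotene. The unconventional myosin Myo7a (log2 0.46, adjusted p = 0.00244) and the BMP antagonist Chrdl1 (log2 0.43, adjusted p = 0.0159) rose less. Dlk2 (log2 0.33, adjusted p = 0.022), Ucp3 (log2 0.32, adjusted p = 0.0194), Slc6a15 (log2 0.31, adjusted p = 0.0343), Reln (log2 0.28, adjusted p = 0.029) and Rcan2 (log2 0.26, adjusted p = 0.0464) also rose.

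All 33 measured interferon response genes had lower values with beta-carotene in knockout females, with a median log2 change of -0.984. Over all genes 19 passed, and adjusted over the list alone 33 passed. The list gave adjusted p = 5.35e-59 with the preset correlation and adjusted p = 0.0197 with an estimated correlation. Its mean per array was 0.85 ± 0.88 on control diet and -0.06 ± 0.24 on beta-carotene (SD, n = 6 each). The difference of -0.92 had exact permutation p = 0.0152, or 0.0486 adjusted over 48 diet and genotype tests. Genotype tests with smaller p lowered this adjusted p, so it does not stand for the diet tests alone. On each of the 5 slides with both diets the mean was lower with beta-carotene, by -0.16 to -1.91. With position as a block the difference was -0.80 ± 0.22 (SE).

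**Figure D1:**
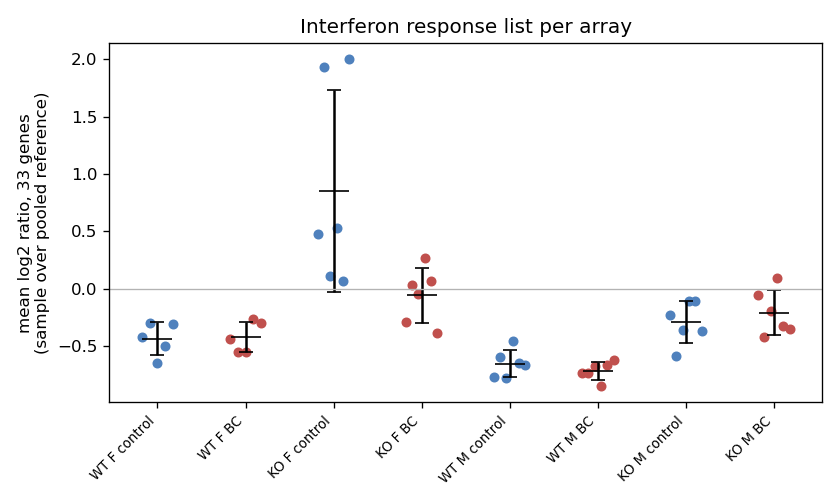
Mean log2 ratio over the pooled reference of 33 interferon response genes, 1 point per array, with group means and SD as bars, control diet in blue and beta-carotene in red. Knockout females on control diet ranged from 0.07 to 2.00, and those on beta-carotene from -0.39 to 0.27.

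Inflammation genes moved the same way in knockout females. Their list of 44 genes had a median log2 change of -0.321, with adjusted p = 5.31e-16 and adjusted p = 0.0197 with an estimated correlation. The acute-phase genes Saa3 (log2 -1.28, adjusted p = 0.0165) and Saa1 (log2 -0.75, adjusted p = 0.00901) passed over all genes, and 14 members were lower and 1 higher adjusted over the list alone. The study's group reported on such genes from these animals, so this is not independent evidence. Ccl17 had a log2 change of 0.41 (adjusted p = 0.357). Interstitial macrophage and monocyte markers had a median of -0.268 (15 genes, adjusted p = 2.88e-08, or 0.134 with an estimated correlation). Of these, Fcgr1 fell (log2 -0.71, adjusted p = 0.0293), 7 passed adjusted over the list alone, and Ly6c1 had -0.57 (adjusted p = 0.0633). Their mean per array differed by -0.29 with exact permutation p = 0.0325, or 0.0975 after adjustment. Without control replicate 5 this list passed with an estimated correlation too (adjusted p = 0.0377).

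Some other lists had lower medians in knockout females, without passing with an estimated correlation. The 31 plasma cell genes had a median of -0.293, none passing over all genes or over the list alone (adjusted p = 2.42e-09, or 0.368 with an estimated correlation), and their mean per array differed by -0.35 with exact permutation p = 0.158, or 0.345 after adjustment. Igkv19-93 was the member with the smallest p (log2 -0.84, adjusted p = 0.128). The 14 erythroid genes had a median of -0.175 (adjusted p = 4.51e-09, or 0.318 with an estimated correlation), where Eraf (log2 -0.98, adjusted p = 0.022) and Trim10 (log2 -0.66, adjusted p = 0.0276) fell and 6 passed over the list alone. Cell cycle genes had a median of -0.114 (39 genes, adjusted p = 6.96e-05, or 0.554 with an estimated correlation), and Rrm1, a subunit of ribonucleotide reductase, fell (log2 -0.30, adjusted p = 0.0114). The median of plasma cell genes was -0.186 without control replicate 2, and that of cell cycle genes -0.054 and -0.190 without control replicates 4 and 5. Erythroid genes had -0.280 and -0.114 without beta-carotene replicates 4 and 5.

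Retinoid genes did not pass in knockout females. The 30 retinoid metabolism genes had a median of 0.004 (adjusted p = 0.412) and the 20 retinoic acid targets also 0.004, with a mean of -0.005 and an upward test (adjusted p = 0.798). Adh1 had a log2 change of 0.17 (adjusted p = 0.678) and the retinoid receptor Rxra of 0.14 (adjusted p = 0.237). Of the lists that the study's group had reported on, Wnt signalling had a median of 0.033 (35 genes, adjusted p = 0.219) and olfactory receptors of -0.022 (142 genes, adjusted p = 0.0578). Protocadherins had 0.061 (33 genes, adjusted p = 0.0219, or 0.442 with an estimated correlation), with 0 passing over all genes or over the list alone.

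The count in knockout females rested on single arrays. Among the arrays on control diet it was 197 without replicate 1, 11 without replicate 2, 235 without replicate 3, 185 without replicate 4, 334 without replicate 5 and 14 without replicate 6. On beta-carotene it was 71 without replicate 1, 64 without replicate 3 and 50 without replicate 6. Slfn4, Rtp4 and Myo7a passed whichever array was left out, while Ifi27l2a, Ifit1, Ifi44, Acod1, Isg15, Oas1f, Irf7, Oasl2, Trim12a, Chrdl1, Dlk2, Ucp3, Slc6a15, Reln and Rcan2 did not pass without control replicate 2, with adjusted p from 0.0714 for Ifi27l2a to 0.28 for Rcan2. Without that array the log2 changes were -1.66 for Ifi27l2a, -1.17 for Isg15, 2.78 for Trim12a and 0.33 for Dlk2. All 15 failed to pass without control replicate 6 as well, with adjusted p from 0.0625 to 0.235. Some also failed without beta-carotene replicate 1 (Irf7, Rcan2, Reln, Slc6a15, Ucp3), 2 (Rcan2), 3 (Chrdl1, Dlk2, Irf7, Rcan2, Reln, Slc6a15, Trim12a), 4 (Dlk2, Rcan2, Reln, Slc6a15, Trim12a), 5 (Rcan2, Slc6a15) or 6 (Dlk2, Irf7, Rcan2, Slc6a15, Trim12a, Ucp3), or control replicate 1 (Dlk2, Trim12a) or 3 (Trim12a), with adjusted p from 0.0509 to 0.115. Isg15 was at 2.71 in control replicate 2, at 3.03 in replicate 6 and at 0.32 to 0.92 in the other 4. With position as a block 11 genes passed, all among the 108. Slfn4 (log2 -1.28, adjusted p = 0.00633), Rtp4 (log2 -1.24, adjusted p = 0.0223) and Rrm1 (log2 -0.32, adjusted p = 0.0335) were among them. Isg15 (log2 -1.30 ± 0.31, SE, adjusted p = 0.0896), Trim12a (log2 3.32 ± 0.77, SE, adjusted p = 0.0778) and Ifi27l2a (log2 -1.70, adjusted p = 0.0916) were not. Neither were Acod1 (log2 -1.45, adjusted p = 0.0591), Ifit1 (-1.37, 0.104), Ifi44 (-1.28, 0.116), Oas1f (-1.24, 0.107), Irf7 (-1.22, 0.186), Oasl2 (-1.19, 0.102), Dlk2 (0.38, 0.0529), Chrdl1 (0.42, 0.106), Ucp3 (0.32, 0.102), Slc6a15 (0.29, 0.186), Reln (0.25, 0.175) and Rcan2 (0.23, 0.301). With slide as a fixed block 42 passed, Isg15 with adjusted p = 0.033, while Trim12a (adjusted p = 0.0884), Dlk2, Slc6a15, Reln, Rcan2, Ifit1 and Irf7 (adjusted p from 0.0509 to 0.114) did not. Ucp3, Slc6a15, Reln and Rcan2 failed under Cy5 alone and the authors' table (adjusted p from 0.0798 to 0.614). With only the 2 groups in the fit, limma called 0.

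In knockout males beta-carotene went with lower levels of a few genes that lie close together on chromosome 15. Fzd6, a receptor for Wnt proteins (38867635 to 38867694), was 2.50-fold lower (log2 -1.32 ± 0.18, SE, n = 6 and 6). Its mean was -0.93 ± 0.38 (SD) on beta-carotene and 0.40 ± 0.35 on control diet. Cthrc1, a secreted protein of matrix-producing cells (38916886 to 38916945), was 2.14-fold lower (log2 -1.09 ± 0.15, SE), and Azin1, which raises polyamine synthesis (38434890 to 38434949), 1.51-fold lower (log2 -0.59 ± 0.11, SE). Dpys, a pyrimidine catabolic enzyme further along the same chromosome (39613077 to 39613136), was 1.31-fold higher (log2 0.39 ± 0.07, SE).

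limma called 6 genes in knockout males, 2 higher and 4 lower, each beyond the control mean in 6 of 6 arrays. Adjusted p was 5.42e-05 for Fzd6, 5.39e-05 for Cthrc1, and 0.0133 each for Azin1, Dpys and Wls. The last, a carrier for Wnt secretion on chromosome 3, was 1.18-fold higher, but another of its probes had the opposite sign, and with the mean of probes Wls changed by 0.03 (adjusted p = 0.994). The transcript D030063E12 (chromosome 15, 38921646 to 38921705, log2 -0.42, adjusted p = 0.0101) was named after its values were seen. Of the 6, 5 had another called gene within 2 Mb (median 0, at most 2 in 1000 random sets). So did 66 of 105 called in knockout females (median 25, at most 42). For the difference between the sexes' diet changes in knockouts it was 8 of 17 (median 0, at most 6). Rrm1 and Trim12a, neighbours on chromosome 7, passed in both. A strain haplotype there was not tested.

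Fzd6 and Cthrc1 passed in knockout males whichever array was left out. The count was 3 without control replicate 3, 10 without beta-carotene replicate 1, 10 without beta-carotene replicate 2 and 18 without beta-carotene replicate 3. Azin1 did not pass without control replicate 1 (adjusted p = 0.0501), control replicate 3 (adjusted p = 0.0701) or beta-carotene replicate 6 (adjusted p = 0.0818). Wls did not pass without control replicate 3 (adjusted p = 0.0697) or control replicate 6 (adjusted p = 0.0814), nor with Feature Extraction's signals, Cy5 alone or the authors' table (adjusted p from 0.057 to 0.11). Azin1 did not with these signals (adjusted p = 0.0745) or the mean of probes (log2 -0.38, adjusted p = 0.527), and Dpys with these signals (log2 1.03, adjusted p = 0.605) or Cy5 alone (adjusted p = 0.108). Dpys did not pass without control replicates 2, 3 or 6 (adjusted p = 0.062, 0.0697 and 0.0514) or beta-carotene replicates 1 or 6 (adjusted p = 0.0578 and 0.0843). With position as a block limma called 0, with Fzd6 at -1.17 ± 0.22 (SE, adjusted p = 0.0542), Cthrc1 at -1.0 ± 0.18 (SE, adjusted p = 0.0542), Azin1 at -0.54 ± 0.13 (SE, adjusted p = 0.782) and Dpys at 0.36 ± 0.09 (SE, adjusted p = 0.782). D030063E12 (log2 -0.31) and Wls (log2 0.21) had adjusted p = 1. Within slides all 6 passed, Fzd6 with adjusted p = 5.51e-05. With only the 2 groups in the fit, limma called 0, against 976 genes at an unadjusted p under 0.05 in the fit to all groups.

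Several lists shifted by small amounts in knockout males. Cardiac muscle genes, which the wall of the pulmonary veins also expresses, had a median of -0.249 (24 genes, all with lower values, none passing, adjusted p = 1.15e-07, or 0.629 with an estimated correlation). Their mean per array differed by -0.27 with exact permutation p = 0.232, or 0.457 after adjustment, and that of the alveolar type II markers by 0.11 with exact permutation p = 0.136, or 0.311 after adjustment. Alveolar type II markers had 0.091 (17 genes, adjusted p = 0.000421, or 0.629 with an estimated correlation), among them Lamp3 (log2 0.28, adjusted p = 0.223), and 1 passed over the list alone. Club cell markers had -0.100 (21 genes, adjusted p = 0.000733, or 0.629 with an estimated correlation), adipose genes -0.150 (17 genes, adjusted p = 0.00136, or 0.798 with an estimated correlation) and alveolar macrophage markers 0.131 (19 genes, adjusted p = 0.00741, or 0.798 with an estimated correlation). Club cell markers (adjusted p = 0.229) and adipose genes (adjusted p = 0.247) did not pass with position as a block. Leaving out control replicate 1 also ended the call of adipose genes (adjusted p = 0.0615), and control replicates 2 and 4 and beta-carotene replicate 6 that of alveolar macrophage markers (adjusted p = 0.088, 0.131 and 0.0788), which the authors' table ended too (adjusted p = 0.052). Medians moved to -0.302 and -0.232 for adipose genes without beta-carotene replicates 3 and 4 and to 0.146, 0.060 and 0.136 for alveolar type II markers without beta-carotene replicate 3 and control replicates 4 and 6. Club cell markers had -0.054, -0.058 and -0.153 without beta-carotene replicates 1, 3 and 5.

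Protocadherins, a family the study's group reported from male lungs of this experiment and so no independent evidence, had a median of 0.041 in knockout males (33 genes, adjusted p = 7.77e-05, or 0.212 with an estimated correlation). None passed over all genes and 6 over the list alone, with Pcdhb9 at 0.30 (adjusted p = 0.0721), and the median was 0.074 without control replicate 1. Their mean per array differed by 0.07 with exact permutation p = 0.013, or 0.0446 after adjustment. Olfactory receptors had a median of 0.014 (adjusted p = 0.293), Wnt signalling of -0.021 with Fzd6 and Cthrc1 passing (adjusted p = 0.108), and inflammation genes of 0.014 (adjusted p = 0.504). Interferon genes had 0.104 (adjusted p = 0.125), retinoid metabolism -0.002, with a mean of 0.005 and a downward test (adjusted p = 0.851), and retinoic acid targets -0.028 (adjusted p = 0.705).

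In wild-type lungs no gene passed for beta-carotene in either sex. limma called 0 of 19379 genes in females, with 817 at an unadjusted p under 0.05 where 969 are expected by chance, and 0 in males, with 211. The genes with the smallest p in females were Qsox2 (log2 -0.26 ± 0.07, SE), the serpin Serpina9 (log2 -0.87 ± 0.22, SE), the innate immune receptor Tlr8 (log2 -0.22), Dlx6os2 (log2 -0.18), the T cell factor Bcl11b (log2 -0.74), the glucocorticoid-activating enzyme Hsd11b1 (log2 0.22 ± 0.06, SE), Ccno of ciliated cells (log2 0.34 ± 0.09, SE), Taf6l (log2 0.29), Cyp4f15 (log2 0.26) and Cabcoco1 (log2 0.27), all with adjusted p = 0.999. In males they were Mkx (log2 0.28 ± 0.08, SE), Nkx2-4 (log2 0.15), Arhgef33 (log2 0.36), Anp32e (log2 0.23), Pde1c (log2 0.19), Brinp2 (log2 -0.17), Maml3 (log2 -0.15), Zfp518b (log2 -0.15), Zmynd15 (log2 -0.20) and Mettl8 (log2 -0.32), all with adjusted p = 1. Under Cy5 alone Qsox2 (log2 0.05) and Arhgef33 (log2 -0.06) had the opposite sign.

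Some lists shifted in wild-type females. Skeletal muscle genes had a median of -0.637 with beta-carotene (15 genes, 9 passing over the list alone, adjusted p = 2.57e-16, or 0.195 with an estimated correlation). Their mean per array was 2.35 in control replicate 1 and 0.51 in control replicate 5, and -0.67 to -0.60 in the other 3 control arrays. By this mean the diet difference was -0.78, with exact permutation p = 0.349. Their median was -0.126 without control replicate 1 (adjusted p = 1.96e-05), and without control replicate 4 they passed with an estimated correlation (adjusted p = 0.0467). Ciliated cell markers had a median of 0.112 (36 genes, adjusted p = 3.47e-06) and T cell markers -0.103 (24 genes, adjusted p = 4.6e-06). Immediate early and heat shock genes had -0.271 (24 genes, adjusted p = 9.29e-06). Dendritic cell genes had -0.128 (17 genes, adjusted p = 1.84e-05) and sterol synthesis genes 0.096 (25 genes, adjusted p = 0.000286). With an estimated correlation each of these lists had adjusted p = 0.514 or 0.641. The last 2 did not pass under Cy5 alone (adjusted p = 0.111 and 0.205). Ciliated cell markers did not pass without control replicate 1 (median 0.058, adjusted p = 0.12) and had 0.061 without beta-carotene replicate 2. The latter array moved dendritic cell genes to -0.077 and sterol synthesis genes to 0.060, beta-carotene replicate 3 moved these to -0.078 and 0.061, and control replicate 5 moved dendritic cell genes to -0.085. T cell markers had -0.069 without beta-carotene replicate 2. In wild-type males, plasma cell genes had -0.135, alveolar macrophage markers 0.102 and immediate early genes 0.139, each with adjusted p = 0.000844 and adjusted p = 0.994 with an estimated correlation. Leaving out control replicate 1 ended the call of plasma cell genes (adjusted p = 0.0538), as did slide as a fixed block (-0.074, adjusted p = 0.136), and control replicate 2 that of alveolar macrophage markers, with the sign reversed (median -0.022, adjusted p = 0.697). Immediate early genes did not pass without control replicate 6 (0.090, adjusted p = 0.0771) or beta-carotene replicate 2 (0.065, adjusted p = 0.0834), and had 0.091, 0.242 and 0.209 without beta-carotene replicates 4, 5 and 6. Retinoid metabolism (0.020 in females, adjusted p = 0.649, and 0.007 in males, adjusted p = 0.78) and retinoic acid targets (0.015, adjusted p = 0.712, and -0.001, with a mean of 0.034 and an upward test, adjusted p = 0.992) did not pass.

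The series title asks about males and females, and the change with diet differed between the sexes of the knockouts for some genes. Fzd6 changed by 0.46 in females and -1.32 in males (difference 1.79 ± 0.26, SE, adjusted p = 0.000124). Cthrc1 changed by 0.33 and -1.09 (difference 1.43 ± 0.21, SE, adjusted p = 0.000124), and Dpys by -0.35 and 0.39 (difference -0.74 ± 0.10, SE, adjusted p = 0.000124). Rtp4 (difference -1.64 ± 0.31, SE, adjusted p = 0.00817) and Slfn4 (difference -1.48 ± 0.28, SE, adjusted p = 0.0089) fell more in females, where they had -1.44 and -1.42, against 0.20 and 0.06 in males.

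limma called 17 genes for this difference, 9 more positive and 8 more negative in females. Trim12a (difference 4.78, adjusted p = 0.0377), the glutamate receptor Gria1 (0.65, adjusted p = 0.0377), Azin1 (0.72, adjusted p = 0.0489), Myo7a (0.58, adjusted p = 0.0119) and Reln (0.51, adjusted p = 0.00761) were among the former. Rrm1 (-0.48, adjusted p = 0.00583), H2-T24 of the class I family (-0.70, adjusted p = 0.0377) and the collagenase Mmp13 (-0.70, adjusted p = 0.0486) were among the latter. The interferon list had a median difference of -1.051, with all 33 genes negative, 0 passing over all genes and 31 over the list alone (adjusted p = 7.18e-35, or 0.233 with an estimated correlation). Across 19173 genes, which are not independent replicates, the changes of the sexes had r = -0.229 with exact permutation p = 0.162. The count was 40, 84, 30 and 151 without replicates 1, 3, 4 and 5 of the knockout females on control diet, and 34 without replicate 3 of the knockout males on beta-carotene. Calls of 5 genes were lost when single knockout arrays were left out. All 5 (Trim12a, Gria1, H2-T24, Azin1 and Mmp13) failed without control females 2 or 6, beta-carotene female 5, control males 1 or 2 or beta-carotene male 4, with adjusted p from 0.052 to 0.123. Further losses came without control female 4 (Azin1), beta-carotene females 1 (Azin1, Mmp13), 2 (Azin1, Gria1, Mmp13), 3 (all but Azin1), 4 (Azin1, Mmp13, Trim12a) and 6 (Azin1, H2-T24, Mmp13). The same held without control males 3 (Azin1), 4 (all but Azin1) and 6 (H2-T24) and beta-carotene males 1 (all but Gria1), 2 (Azin1, H2-T24, Trim12a), 5 (H2-T24, Mmp13, Trim12a) and 6 (all but H2-T24), with adjusted p from 0.0525 to 0.105. With the mean of probes the 5 failed too (adjusted p up to 0.149), as did Rrm1 under Cy5 alone (0.0795) and the authors' table (0.0502). With the position block, Fzd6, Cthrc1 and Dpys passed (adjusted p = 0.00913 each), and limma called these 3 alone. Rtp4 and Slfn4 had adjusted p = 0.12, Rrm1, H2-T24 and Reln adjusted p = 0.169, Myo7a 0.183, Trim12a 0.346, Gria1 0.47, Azin1 0.49 and Mmp13 0.498.

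Other lists differed between the sexes' diet changes as well, each with a preset correlation only. In knockouts inflammation genes, not independent evidence, had a median difference of -0.359 (7 passing over the list alone, adjusted p = 7.01e-09, or 0.233 with an estimated correlation) and interstitial macrophage and monocyte markers -0.410 (5 passing over the list alone, adjusted p = 2.07e-06, or 0.278 with an estimated correlation). Plasma cell genes had -0.357 (adjusted p = 1.14e-05, or 0.547 with an estimated correlation), cell cycle genes -0.156 with Rrm1 passing (adjusted p = 1.94e-05, or 0.547 with an estimated correlation) and sterol synthesis genes -0.221 (adjusted p = 2.73e-05, or 0.510 with an estimated correlation). In wild types skeletal muscle genes had -0.622 (adjusted p = 5.62e-10, or 0.488 with an estimated correlation), immediate early genes -0.430 (adjusted p = 9.78e-09, or 0.396 with an estimated correlation) and T cell markers -0.138 (adjusted p = 7.09e-05, or 0.966 with an estimated correlation). Ciliated cell markers had 0.101 (adjusted p = 0.000623), plasma cell genes 0.228 (adjusted p = 0.0119) and club cell markers 0.162 (adjusted p = 0.0179), all with adjusted p = 0.966 with an estimated correlation. Without replicate 1 of the wild-type females on control diet skeletal muscle genes had -0.097 (adjusted p = 0.0099), and neither ciliated (adjusted p = 0.31) nor club cell markers (adjusted p = 0.398) passed. Cell cycle genes in knockouts had -0.102 without control female 4. In wild types T cell markers had -0.081, -0.059 and -0.090 without control female 5, control male 3 and beta-carotene male 6. Ciliated cell markers did not pass without beta-carotene female 2 (adjusted p = 0.0985), and plasma cell genes did not without beta-carotene female 5 (adjusted p = 0.403), control female 2 (0.108) or control male 1 (0.0677). Club cell markers also failed without beta-carotene females 2 or 3, control female 2, beta-carotene male 5 or control male 4 (adjusted p from 0.0542 to 0.169). Position as a block ended the calls of cell cycle genes in knockouts (-0.049, adjusted p = 0.0823) and of T cell (-0.025, 0.118) and club cell markers (0.098, 0.511) in wild types, and slide as a fixed block that of plasma cell genes (0.043, 0.86).

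Between the genotypes the diet change differed in males for Fzd6 (knockout minus wild type -1.35 ± 0.26, SE) and Cthrc1 (-1.08 ± 0.21, SE), both with adjusted p = 0.048. These 2 were the only genes limma called, and neither passed with position as a block (adjusted p = 0.824 each) or slide as a fixed block (adjusted p = 0.0587 and 0.0855). The count was 0 without any single array, except that it was 2 without control replicate 4 and 3 without beta-carotene replicate 3 of the knockout males. Dpys (0.46), Azin1 (-0.68) and Pcdhb9 (0.41) had adjusted p = 0.306. In females limma called 0 genes for this difference, with 1132 at an unadjusted p under 0.05. Slfn4 (-1.46, adjusted p = 0.23) and Rtp4 (-1.52, adjusted p = 0.245) had the smallest p, and 26 of 33 interferon genes passed over the list alone (median -0.966, adjusted p = 1.69e-33, or 0.298 with an estimated correlation). The count in females was 7 without control replicate 3 and 1 without control replicate 5 of the knockouts. Skeletal muscle genes (0.827, adjusted p = 5.12e-09), sterol synthesis genes (-0.224, adjusted p = 8.48e-08) and inflammation genes (-0.183, adjusted p = 9.88e-07) each had adjusted p = 0.344 with an estimated correlation, and the first had 0.257 without replicate 1 of the wild-type females on control diet (adjusted p = 0.000762). Plasma cell genes had -0.349 (adjusted p = 7.92e-07, or 0.614 with an estimated correlation) and immediate early genes 0.398 (adjusted p = 0.000182, or 0.596 with an estimated correlation). In males protocadherins, not independent evidence, had 0.074 (2 passing over the list alone, adjusted p = 0.000337, or 0.357 with an estimated correlation). Immediate early genes (-0.288, adjusted p = 0.000247), cardiac muscle genes (-0.217, adjusted p = 0.000805), cell cycle genes (0.087, adjusted p = 0.015), club cell markers (-0.080, adjusted p = 0.0175) and plasma cell genes (0.160, adjusted p = 0.0177) had adjusted p = 0.929 with an estimated correlation. The last 4 rested on single males. Without knockout control males 1 and 2 cardiac muscle genes had -0.097 (adjusted p = 0.066) and -0.139 (adjusted p = 0.0388). Cell cycle genes failed without knockout control male 2, knockout beta-carotene male 6, wild-type control males 4 or 5 or wild-type beta-carotene male 1 (adjusted p from 0.0613 to 0.165). Plasma cell genes failed without knockout control males 2 or 3, knockout beta-carotene males 3 or 6, wild-type control male 1 or wild-type beta-carotene male 4 (adjusted p from 0.0662 to 0.27). Club cell markers failed without knockout control males 3 or 4, knockout beta-carotene males 1 or 2 or wild-type beta-carotene males 1 or 6 (adjusted p from 0.0553 to 0.0839), and had -0.128 and -0.132 without knockout beta-carotene male 5 and control male 6. Position as a block ended the calls of cardiac muscle genes (-0.087, adjusted p = 0.26) and club cell markers (-0.045, 0.316), and slide as a fixed block those of cell cycle (0.062, 0.156) and plasma cell genes (0.109, 0.187). Among wild types limma called 0 genes for a difference of the sexes, with 422 at an unadjusted p under 0.05.

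Knockout and wild-type lungs on control diet differed widely in both sexes. The goblet cell gene Clca1 was 10.5-fold higher in knockout females (log2 3.39 ± 0.69, SE, n = 6 and 5, adjusted p = 0.000362) and 8.13-fold higher in knockout males (log2 3.02 ± 0.66, SE, n = 6 and 6, adjusted p = 0.00109). Htatip2 (chromosome 7, 49638930 to 49640617) was 9.18-fold lower in knockout females (log2 -3.20 ± 0.24, SE, adjusted p = 1.96e-13) and 8.02-fold lower in knockout males (log2 -3.00 ± 0.23, SE, adjusted p = 2.66e-13). The matrix protein Tnn, the histone H2bc18, the histidine-degrading enzyme Hal and Rrp7a were lower by 4.2-fold or more in both sexes. limma called 2859 genes in females, 1558 higher and 1301 lower, and 2035 in males, 969 higher and 1066 lower. In both sexes 651 genes were higher, against 77.9 expected by chance, and 647 lower, against 71.6, and 1 gene went opposite ways.

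After Clca1, the largest rises in knockout females included many interferon genes. Ifi27l2a was 7.55-fold higher (adjusted p = 6.29e-07), Cxcl10 6.54-fold (adjusted p = 2.09e-05), Ifi202b 6.46-fold (adjusted p = 3.37e-08), the neutrophil chemokine Cxcl5 5.19-fold (adjusted p = 0.000985), Isg15 4.74-fold (adjusted p = 3.89e-07), Rsad2 4.64-fold (adjusted p = 7.92e-09), Oas1f 4.21-fold (adjusted p = 3.04e-06) and Ifit1 4.21-fold (adjusted p = 1.24e-05). The plasma protein Afm was higher too (adjusted p = 1.23e-06), with no fold given since no wild-type array of this comparison had it above background. Of 33 interferon genes 31 rose, or 32 over the list alone, with a median of 1.238 (adjusted p = 2.76e-30, or 0.0866 with an estimated correlation). Their mean per array was 1.93 and 2.00 in knockout replicates 2 and 6 and 0.07 to 0.53 in the other 4 knockouts. Of 44 inflammation genes, not independent evidence here, 28 rose and 2 fell (29 and 2 over the list alone, median 0.503, adjusted p = 1.79e-12, or 0.0866 with an estimated correlation), among them Lcn2 (log2 1.51, adjusted p = 5.25e-07). Interstitial macrophage and monocyte markers had a median of 0.465 (11 of 15 rose, 12 over the list alone, adjusted p = 1.11e-08, or 0.0866 with an estimated correlation), with Ms4a7 at 1.45 (adjusted p = 1.32e-06) and Fcgr1 at 1.29 (adjusted p = 4.19e-07). Without knockout replicate 5 these 3 lists had adjusted p = 0.0469 with an estimated correlation.

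Alveolar type II markers were higher in knockout females as well, 11 of 17 over all genes and 13 over the list alone (median 0.287, adjusted p = 6.38e-08, or 0.0866 with an estimated correlation). Lamp3 rose by 0.52 (adjusted p = 9.82e-07) and the surfactant protein Sftpd by 0.76 (adjusted p = 1.14e-05). Cardiac muscle genes fell, 12 of 24 over all genes and 14 over the list alone (median -0.482, adjusted p = 7.16e-09, or 0.381 with an estimated correlation), led by Myh7 (log2 -1.72, adjusted p = 7.54e-14). The sugar enzyme Fbp2 was lower (adjusted p = 1.28e-11), with the knockouts below background, and Trim12a lower in 4 of 6 arrays (log2 -2.60, adjusted p = 0.0137). Skeletal muscle genes had a median of -1.040 (10 of 15 lower over all genes, 13 over the list alone, adjusted p = 1.96e-06, or 0.414 with an estimated correlation). Of these, Tnnt3 (log2 -1.83, adjusted p = 0.0031), Tnnc2 (log2 -2.00, adjusted p = 0.0234) and Myh1 (log2 -1.85, adjusted p = 0.0157) belonged to the genes named by rule. The list had a median of -0.383 without wild-type replicate 1 (adjusted p = 0.000886). Tnnc2 and Myh1 did not pass without wild-type replicate 1 (log2 -0.97, adjusted p = 0.152, and log2 -0.88, adjusted p = 0.134) or replicate 5 (log2 -1.54, adjusted p = 0.124, and log2 -1.56, adjusted p = 0.0696), or with position as a block (adjusted p = 0.1 and 0.0838).

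In knockout males the antimicrobial lectin Reg3g of airway epithelium was 5.95-fold higher (log2 2.57 ± 0.33, SE, n = 6 and 6, adjusted p = 1.11e-07). The fibrinogen chain Fgg was 3.27-fold higher (adjusted p = 3.02e-07), Ifi202b 3.12-fold (adjusted p = 0.000161), Rab6b 3.07-fold (adjusted p = 7.22e-18), the mitochondrial arginase Arg2 2.71-fold (adjusted p = 9.15e-10), Rsad2 2.61-fold (adjusted p = 4.21e-05) and Disp2 2.36-fold (adjusted p = 1.68e-09). Afm was higher as well (adjusted p = 1.71e-06), again with wild types below background. The airway secretory protein Bpifa1 was 3.13-fold higher (adjusted p = 0.0165), but it did not pass without wild-type replicate 6 (log2 1.32, adjusted p = 0.076) or with position as a block (log2 1.19, adjusted p = 0.115). Lower were Myh7 by 3.49-fold (adjusted p = 3.2e-15), the transcription factor Sox11 by 3.40-fold (adjusted p = 3.81e-12), the ribosomal protein gene Rps4l by 3.19-fold (adjusted p = 1.61e-16), and Zfp982 by 3.50-fold (adjusted p = 6.9e-13), where another probe of Zfp982 had the opposite sign. Fbp2 was lower too (adjusted p = 1.67e-10), with the knockouts below background.

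Alveolar type II markers rose in knockout males too, 8 of 17 over all genes and 12 over the list alone (median 0.253, adjusted p = 1.58e-07, or 0.189 with an estimated correlation), among them Hc (log2 0.64) and Sftpa1 (log2 0.58). Alveolar macrophage markers had a median of 0.184 (8 of 19 rose, 9 over the list alone, adjusted p = 1.72e-06, or 0.353 with an estimated correlation), with the lipid receptor Trem2 at 0.96 and the protease Ctsk at 0.61. This median was 0.298, 0.118 and 0.099 without knockout replicates 4 and 5 and wild-type replicate 2. Natural killer and cytotoxic genes had 0.267 (6 of 16 rose, 9 over the list alone, adjusted p = 3.93e-06, or 0.405 with an estimated correlation). Inflammation genes, not independent evidence, had 0.335 (11 rose and 1 fell, 12 and 1 over the list alone, adjusted p = 1.36e-06, or 0.353 with an estimated correlation), with Ccl6 at 1.02, Ccl17 at 0.92 and the homeostatic chemokine Ccl19 at -1.03. Interferon genes had 0.279 (3 of 33 rose, also 3 over the list alone, adjusted p = 7.75e-05, or 0.754 with an estimated correlation). Protocadherins, not independent evidence, had -0.157 in males (9 of 33 fell, 15 over the list alone, adjusted p = 2.2e-05, or 0.188 with an estimated correlation) and -0.157 in females (12 fell, 16 over the list alone, adjusted p = 0.000111, or 0.0866 with an estimated correlation). By exact permutation of means per array, interferon (1.29 in females and 0.36 in males), inflammation (0.63 and 0.34), interstitial macrophage (0.55 and 0.29), alveolar type II (0.35 and 0.31) and protocadherin genes (-0.15 and -0.16) passed in both sexes, with adjusted p of 0.0207 to 0.024. Cardiac (-0.68) and skeletal muscle genes (-0.96) passed in females (adjusted p = 0.0207) and not in males (-0.35, adjusted p = 0.258, and -0.13, adjusted p = 0.307), and plasma cell genes in neither (0.17, adjusted p = 0.641, and -0.16, adjusted p = 0.558).

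The genotype difference differed between the sexes for 1 gene, the chemokine Cxcl12 (chromosome 6, 117146828 to 117146887). Cxcl12 was lower in knockout females (log2 -0.37, adjusted p = 0.00321) and higher in knockout males (log2 0.36, adjusted p = 0.00386), a difference of -0.73 ± 0.13 (SE, adjusted p = 0.0175). This did not pass under Cy5 alone (adjusted p = 0.231), the authors' table (0.205), the mean of probes (log2 -0.46, 0.293) or slide as a fixed block (0.0888). limma gave 1478 genes at an unadjusted p under 0.05 here, with Sowaha (0.42), Mrgbp (0.28), Rtp4 (1.40), Oas1b (0.65) and the inflammasome gene Nlrp3 (-0.40) at adjusted p = 0.244 and Adar (0.74), Edn1 (-0.97), Hamp (-0.92), Nipal2 (-0.31) and Cd209d (-0.64) at adjusted p = 0.316. Interferon genes had a median difference of 0.913, with 0 passing over all genes and 31 over the list alone (adjusted p = 1.73e-29, or 0.464 with an estimated correlation). Skeletal muscle genes (-0.858, adjusted p = 6.42e-07), plasma cell genes (0.322, adjusted p = 0.000173), glucocorticoid stress genes (-0.647, adjusted p = 0.000256) and inflammation genes (0.203, adjusted p = 0.000581) had adjusted p = 0.549 with an estimated correlation, and cardiac muscle genes (-0.270, adjusted p = 0.000763) adjusted p = 0.577. Without replicate 1 of the wild-type females skeletal muscle genes had -0.246 (adjusted p = 0.00225), and without replicate 1 of the knockout males cardiac muscle genes had -0.163 (adjusted p = 0.0248). Slide as a fixed block ended the calls of plasma cell (0.187, adjusted p = 0.0781), glucocorticoid stress (-0.278, 0.101) and inflammation genes (0.081, 0.148). The count was 0 without replicates 2, 3, 4 or 5 of the wild-type females, replicate 4 of the knockout females, replicates 1 or 2 of the wild-type males or replicate 3 of the knockout males, all on control diet. It was 10 without replicate 3 of the knockout females and 2 without their replicate 5 or replicate 2 of the knockout males.

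Averaged over sexes and diets, knockout and wild type differed in 6250 genes, 3005 higher and 3245 lower, of which 91 by more than 2-fold. Clca1 (9.53-fold, adjusted p = 1.28e-10), Ifi202b (3.81-fold), Reg3g (3.63-fold), Fgg (3.25-fold), Rab6b (3.11-fold, adjusted p = 2.76e-29), Rsad2 (2.84-fold), Cxcl10 (2.79-fold), the kallikrein Klk1b24 (2.66-fold) and Cxcl5 (2.62-fold) led the rises. Htatip2 (8.40-fold, adjusted p = 2.7e-24), H2bc18 (5.49-fold), Tnn (5.28-fold), Rrp7a (4.58-fold), Hal (4.35-fold), Trim12a (4.04-fold), Zfp982 (3.41-fold), Myh7 (3.37-fold) and Exd1 (3.18-fold) led the falls. Afm, higher, and Fbp2, lower, were among the largest changes as well, without a fold since some groups were below background. Alveolar type II markers rose in 15 of 17 genes (also 15 over the list alone, median 0.280, adjusted p = 4.2e-10, or 0.108 with an estimated correlation). Inflammation genes, not independent evidence, rose in 33 of 44 and fell in 2 (34 and 2 over the list alone, median 0.350, adjusted p = 5.6e-11, or 0.108 with an estimated correlation). Interstitial macrophage and monocyte markers rose in 11 of 15 (also 11 over the list alone, median 0.320, adjusted p = 7.22e-08, or 0.120 with an estimated correlation). Interferon genes rose in 30 of 33 (31 over the list alone, median 0.53, adjusted p = 8.63e-15, or 0.378 with an estimated correlation) and cardiac muscle genes fell in 19 of 24 (23 over the list alone, median -0.470, adjusted p = 1.45e-09, or 0.378 with an estimated correlation).

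Retinoid genes changed singly rather than as lists between the genotypes. The retinoic acid receptor Rarb was lower (log2 -0.49 ± 0.05, SE, adjusted p = 4.98e-12), as were the retinol dehydrogenase Adh7 (log2 -0.89, adjusted p = 3.44e-11), the retinol carrier Rbp4 (log2 -0.39, adjusted p = 4.28e-10) and Rarres1 (log2 -0.18, adjusted p = 0.000133), while Aldh1a2, which makes retinoic acid, was higher (log2 0.36, adjusted p = 2.11e-08). Of 20 retinoic acid targets 5 fell and 0 rose, also over the list alone (median -0.051, adjusted p = 0.112). Of 30 retinoid metabolism genes 8 rose and 5 fell, also over the list alone, with a median of 0, a mean of -0.019 and an upward test (adjusted p = 0.763). Sterol synthesis genes had a median of 0.105 (13 rose and 1 fell, 14 and 1 over the list alone, adjusted p = 0.00619, or 0.571 with an estimated correlation). Steroid hormone metabolism had -0.036 (adjusted p = 0.205), olfactory receptors 0.016 (adjusted p = 0.176) and Wnt signalling 0.021 (adjusted p = 0.72).

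Female and male lungs differed in natural killer cell, interferon and ciliated cell genes. Gzma, a protease of cytotoxic cells, was 1.78-fold higher in females (log2 0.83 ± 0.08, SE, n = 22 and 24, adjusted p = 1.23e-10) and Gzmb higher by 0.72 (adjusted p = 3e-11). Of 16 natural killer and cytotoxic genes 14 were higher, or 15 over the list alone, with a median of 0.350 (adjusted p = 2.28e-29, or 0.00895 with an estimated correlation). Of 33 interferon genes 24 were higher (31 over the list alone, median 0.426, adjusted p = 2.09e-23). So were 18 of 36 ciliated cell markers (28 over the list alone, median 0.129, adjusted p = 1.24e-15). Both lists had 0.194 with an estimated correlation. The interferon difference was largest in knockouts on control diet (females 0.07 to 2, males -0.59 to -0.11 per array).

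limma called 1490 genes between the sexes, 857 higher and 633 lower in females, 10 of them by more than 2-fold. Xist (log2 7.54) and the Y-linked Eif2s3y (log2 -5.97), Ddx3y (log2 -4.82), Kdm5d (log2 -2.05) and Uty (log2 -1.42) had the largest changes. Ifi27l2a (2.32-fold, adjusted p = 3.79e-05), Oas2 (2.01-fold, adjusted p = 7.27e-06), Ifi44 (1.90-fold), Oas1f (1.86-fold), Isg15 (1.74-fold), Rtp4 (1.73-fold), Oasl2 (1.72-fold) and Clca1 (2.33-fold, adjusted p = 0.0179) were higher in females. The protease inhibitor Serpina3m (2.07-fold, adjusted p = 1.33e-16), the platelet genes Gp9 (1.88-fold, adjusted p = 3.42e-07), Ppbp (1.77-fold) and Treml1 (1.65-fold), the esterase Ces1g (1.69-fold) and the neutrophil peptide Camp (1.58-fold, adjusted p = 0.028) were lower. T cell markers had a median of 0.148 (8 of 24 higher, 14 over the list alone, adjusted p = 7.26e-07, or 0.507 with an estimated correlation) and cell cycle genes 0.113 (8 of 39 higher, 17 over the list alone, adjusted p = 7.32e-07, or 0.627 with an estimated correlation). Xenobiotic and Nrf2 target genes had -0.069 (7 of 33 lower and 1 higher, 15 and 1 over the list alone, adjusted p = 1.5e-06, or 0.194 with an estimated correlation), among them Gsta3 (log2 -0.30, adjusted p = 3.79e-05). Without replicate 1 of the knockout females on beta-carotene this list passed with an estimated correlation (adjusted p = 0.00216). Slides held mostly 1 sex. With slide as a random block 838 genes passed, and as a fixed block 128, where Clca1, Ifi27l2a, Oas2, Ifi44, Oas1f, Isg15, Oasl2, Ppbp, Treml1 and Camp did not pass (adjusted p from 0.0624 for Treml1 to 0.783 for Clca1).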

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

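The tests of strain haplotypes, array position and diet for the genes on chromosome 15, those of immune cells and diet for the interferon genes, and the splits within slides were chosen only after the result was seen. The measures checked for samples far from their group were chosen after their values were seen as well. They were 15 measures in 108 group tests, of which 15 pointed to a sample and 5.4 are expected to by chance.

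In replicate 2 of the knockout females on beta-carotene the spread of log2 ratios was 0.166, against 0.226 to 0.257 in the other arrays of its group. Bco1 was at 0.0174 there, against 0.238 to 0.343, Ddx3y at -2.42, against -4.18 to -3.94, and Eif2s3y at -2.97, against -5.15 to -4.73. Xist was at -4.16 in replicate 4 of the wild-type males on control diet, against -7.14 to -6.51, and at -2.89 in replicate 3 of the knockout males on beta-carotene, against -7.44 to -6.87. The skeletal muscle mean was at -0.249 in the former, against -0.636 to -0.517, and at -0.154 in the latter, against -0.85 to -0.74. In the latter array Fzd6 was at -0.212, against -1.24 to -0.873, Cthrc1 at -0.0778, against -1.3 to -1.02, and Trim12a at -1.3, against -3.99 to -3.78. Fzd6 was at -1.15 in replicate 3 of the knockout females on control diet, against -0.12 to 0.326. Isg15 was at 0.0179 in replicate 4 of the knockout males on beta-carotene, against -0.722 to -0.454. The adipose mean was at -0.407 in replicate 5 of the wild-type females on beta-carotene, against 0.144 to 0.312, and at 0.839 in replicate 1 of the knockout females on control diet, against -0.666 to -0.23.

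Differences between groups were tested as such. The diet change differed between the sexes of the knockouts for 17 genes and between the genotypes in males for 2, and the genotype difference differed between the sexes for 1.

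Of the 6 genes that changed with diet in knockout males, 5 lay together on chromosome 15. A slide position effect would lower Fzd6 at positions 1 and 4 in wild types too, but there the difference was -0.019 (12 and 10 arrays, two-sided permutation p = 0.793), which argues against position as the whole cause. With position as a block Fzd6 changed by -1.17 ± 0.22 (SE), not -1.32 ± 0.18, and lost its call. A strain haplotype may have segregated in the knockout line and been shared unequally by the diet groups. Of the 20 genes that followed Fzd6 best within knockout groups 3 lay within 5 Mb, against 0.057 expected. Only 1 did without the called genes, so this cannot be told apart from a diet effect. In knockout females Fzd6 changed by 0.463 without passing and was low in 1 control. There Dpys fell (log2 -0.35, adjusted p = 0.0114, or 0.151 with the position block), opposite to males. A diet effect in males stays open.

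Interferon genes were lower with beta-carotene in knockout females. With position as a block their mean still differed by -0.8, which argues against position, and the lowest median among the immune cell lists was -0.293, against -0.984 for the interferon genes, which argues against a mere change in the share of immune cells. The difference by diet had exact permutation p = 0.0152. Cage and litter are not given, so an infection or stimulus shared by some control cage mates cannot be told apart from the diet. Isg15 was highest in control replicates 2 and 6, and without them in turn 11 and 14 genes passed in place of 108, while the change of Isg15 went from -1.45 to -1.17 and -1.10.

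Between knockout and wild type 6250 genes differed. Strain variants segregating within the knockout line would give more variable genes there, but the ratio of genes more variable in knockouts to those more variable in wild types was 0.997 (590 and 592), or 667 and 439 without replicate 1 of the wild-type females on control diet, which argues against them as the cause of most differences. They may act on fewer genes, since 376 of 587 genes more variable in knockouts had another such gene within 1 Mb, against a median of 310 and at most 352 in 1000 random sets, and 313 of the 590 were also called between the genotypes. A linked segment of the other strain would give more calls near Bco1. The share called within 10 Mb was 0.867 times that of other genes (28% of 200 and 32.3% of 18999). On the rest of chromosome 8 it was 41.1% of 760. Other genes may carry fixed strain differences too, so a segment stays open. Loss of the enzyme (retinoic acid targets at adjusted p = 0.112) cannot be told apart from untested strain differences fixed in the knockout line. Every knockout differed from every wild type in both.

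Other splits of the same samples were drawn 100 times per comparison, the real one included, and those calling at least as many genes were counted. Chance could not be excluded for diet in knockout females (5 splits with 108 or more, highest other 1975). The same held for the sexes' difference in genotype change (9 with 1 or more, highest other 2145). For diet in knockout males 4 splits called 6 or more (highest other 532), so chance could be excluded only narrowly. These splits ignored the slides, on which arrays of both diets lay side by side. With diets exchanged only within slides, 3 of 72 splits of knockout females called 108 or more (highest other 180), but 7 reached the 42 of the fit with slide as a fixed block (highest other 426). In knockout males 2 of 32 called 6 or more (highest other 9) and 1 the 12 of that fit (highest other 9). These disagreed, so chance, a haplotype shared unequally included, stays open for both groups. Chance also stays open for the sexes' difference in the diet change of knockouts (2 splits with 17 or more, highest other 587). The same holds for the genotypes' difference in males (1 with 2, highest other 0), as neither was split within slides. Chance could be excluded for genotype in females (1 split with 2859, highest other 2260) and males (1 with 2035, highest other 680). It could also be excluded for genotype overall (1 with 6250, highest other 2) and sex (1 with 1490, highest other 3). For diet in knockouts and the sexes' differences in diet and genotype change another split called many times the real count. This may point to a structure of the samples other than these groups, which was not tested. Where limma called 0, all 100 splits called as many. The highest other count was 2 for diet in wild-type females (817 genes at an unadjusted p under 0.05), 6 in wild-type males (211), 1 for the sexes' difference in wild types (422) and 15 for the genotypes' difference in females (1132).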

How the results depend on the processing

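The array position block, the fit without 3 doubtful arrays and the lists without single arrays were chosen only after the result was seen. A block for scan date was planned but not run, since all arrays were scanned on 1 day. Counts were compared with the values in the report, which were 108 for diet in knockout females, 6 in knockout males, 17 for the sexes' difference between these, 2 for the genotypes' difference in males, 2859 and 2035 for genotype in females and males, 1 for the sexes' difference in genotype change, 6250 for genotype overall and 1490 for sex. Counts not given below moved by 1.5 times at most, and the 4 comparisons in which limma called 0 (817, 211, 422 and 1132 genes at an unadjusted p under 0.05) stayed at 0, except for the genotypes' difference in females when 1 array was left out. The cause of the changes below was not tested except where said.

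With array position as a block the count was 11 for diet in knockout females, 0 in knockout males, 3 for the sexes' difference between these and 0 for the genotypes' difference in males, and the cell cycle list in the last reversed to -0.034 (adjusted p = 0.306). In knockout males position and diet coincide by design, so the block takes up part of the diet change and widens the error of Fzd6 from 0.18 to 0.22. Without the doubtful arrays diet in knockout males gave 17 and the sexes' difference 33. Slide as a fixed block gave 42 for diet in knockout females, 12 in knockout males, 0 for the genotypes' difference in males, 0 for the sexes' difference in genotype change and 128 for sex, since slides held mostly 1 sex. Slide as a random block gave 13 for diet in knockout males, 52 for the sexes' difference between knockouts' diet changes and 838 for sex. A replicate block gave 10, 26 and 2555 for these. Pairing by number held in part, and same-numbered knockouts of a sex mostly shared a slide. Arrays with the same number had correlations down to -0.091 in females and -0.314 in males. Their medians of 0.0887 and 0.121 exceeded those of other pairs (-0.0184 and -0.038), with 15 of 31 and 21 of 36 pairs over 0.1. For 24 of 46 arrays the best partner had the same number.

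Fitting only the compared groups took the spread from those groups alone, from fewer arrays. It gave 0 for diet in knockout females, 0 in knockout males, 1 for the sexes' difference, 1 for the genotypes' difference in males, 1495 for genotype in females and 0 for the sexes' difference in genotype change. The last was also 0 under Cy5 alone, the authors' table and the mean of probes, and 2 with no background subtraction. Cy5 alone gave 921 for sex, and under it Qsox2 reversed to 0.05 in wild-type females (adjusted p = 0.878) and Arhgef33 to -0.06 in wild-type males (adjusted p = 1). Without single arrays diet in knockout females ranged from 11 to 334, diet in knockout males from 3 to 18, the sexes' difference between these from 12 to 151, the genotypes' difference from 0 to 7 in females and 0 to 3 in males, and the sexes' difference in genotype change from 0 to 10, with the arrays named beside each result in the report.

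Of 185 values for named genes, 182 kept their direction and side of the threshold with no background subtraction, 175 with Feature Extraction's signals, 170 under Cy5 alone, 182 with no filter, 175 with the mean of probes, 162 with slide as a fixed and 184 as a random block, 183 with the replicate block, 141 with only the compared groups, 148 with position as a block and 182 without the doubtful arrays, and 175 of 183 under the authors' table. Of 75 calls for lists 3 passed with the estimated correlation, and 67 (slide as a fixed block, position) to 75 (no filter, mean of probes) kept theirs under the others tried for lists. Without single arrays 1582 of 1620 list values kept direction and call, 37 lost the call, and alveolar macrophage markers in wild-type males reversed to -0.022, with up to 0.147 without control replicate 5. The correlation of the diet changes of knockout females and males ranged from -0.272 to -0.079. The share of probes well above background, 50.3% to 71.4% for Cy5, limits what can be seen of dim genes, and 29214 of 41174 probes were kept.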

Other observations

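The genes and lists in this part were chosen after their values were seen. Between the genotypes, averaged over sexes and diets, cell cycle genes were higher in knockouts, with a median of 0.146 (23 of 39 higher and 2 lower, 26 and 2 adjusted over the list alone, adjusted p = 2.93e-05, or 0.571 with an estimated correlation). B cell markers had a median of 0.249 (9 of 19 higher, also over the list alone, adjusted p = 0.0012, or 0.577 with an estimated correlation), and dendritic cell genes 0.202 (8 of 17 higher, 10 over the list alone, adjusted p = 1.12e-06, or 0.134 with an estimated correlation). Smooth muscle genes had a median of -0.162 (10 of 16 lower, also over the list alone, adjusted p = 0.00131, or 0.445 with an estimated correlation). Ciliated cell markers had -0.093 (16 of 36 lower and 1 higher, 16 and 2 over the list alone, adjusted p = 0.00159, or 0.571 with an estimated correlation).

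Some genes varied far more among knockouts of the same group than among wild types. The phosphatase Ptprg (chromosome 14) had a within-group SD of 2.74 in knockouts and 0.12 in wild types, Trim12a 1.79 and 0.13, Gdpd3 (chromosome 7) 1.18 and 0.11, Slx1b beside it 1.5 and 0.17, Plac9a (chromosome 14) 0.71 and 0.06, Pttg1 0.72 and 0.08 and Cuedc1 0.92 and 0.11. Near Bco1, the DNA repair gene Fanca was lower in knockouts (log2 -0.86, adjusted p = 2.07e-19).

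The genotype difference of females on control diet and the diet change of knockout females share their control arrays, and 90 genes were higher in knockouts and lower with beta-carotene, against 7.56 for independent lists, a number that leaves out the shared arrays, so the excess does not measure a shared effect. With the 6 control arrays divided between the comparisons the overlap was 0 to 129 genes over 20 divisions (median 8.5, against a median of 0.611 for independent lists), and 5 divisions called 0 genes lower with beta-carotene. Across genes these changes had r = -0.565, against -0.476 in simulations with no diet or genotype effect and independent genes, and a covariance of -0.019, against -0.00516. With the divided arrays r was -0.319 (-0.47 to -0.0897) and the covariance -0.0124.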
